A study of Mus musculus with 12 samples.

How the data were processed

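RNA of unfractionated bone marrow, flushed from tibia and femur, was measured on Affymetrix mouse arrays in 12 mice. The mice were 3 wild-type C57Bl/6 mice, 3 lacking Fancc (Fancc-/-), 3 lacking Fancg (Fancg-/-) and 3 lacking both (double knockout). Each mouse gave 1 array and no RNA was pooled. Per the labels, total RNA was amplified from an oligo-dT primer carrying a T7 promoter and hybridized as biotin-labelled cRNA. The input was 2 µg of RNA, except for Fancg-/- replicate 3, with 0.91 µg. The labels give no sex of the mice and no array date.

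The deposited values are log2 signals per probe set, made by the authors with RMA (background adjustment, quantile normalization and summarization across the arrays). Their notes name RMA and Partek without versions. The table held 45101 probe sets, of which 64 were array controls, and none of its sample columns was left unmapped. Values ran from 2.43 to 14.6 and the array medians from 4.79 to 4.87. An array signal is not a count, so precision is limited by the number of arrays, 3 per group. Probe sets with exactly 1 gene symbol were used (34945), and the 932 with several symbols and the 9160 with none were not used here. Of the single-symbol probe sets, 34741 matched the reference gene table (GRCm38.p6) by Entrez ID, and 0 symbols were changed by the match. Each of the 18193 genes was represented by its probe set with the highest mean. A gene was tested if that probe set was above the array median (the percentile 50) on at least 3 arrays. This left 11908 genes, and 6285 dim genes were not tested. Fancc, Fancg and the sex-linked genes Xist, Eif2s3y, Kdm5d and Uty were read on every probe set, whatever the filter. Ddx3y, also planned, had no probe set under its symbol.

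Genes were compared with limma 3.58.1 in R 4.3.3, in 1 linear model over the 12 arrays with moderated variances and a variance trend. The model had 8 residual degrees of freedom. There were 7 comparisons: each knockout with wild type, the double knockout with each single knockout, the single knockouts with each other, and the interaction. The interaction is the double-knockout change minus the sum of both single-knockout changes. Tests were 2-sided, p values were adjusted by Benjamini-Hochberg over the genes of a comparison, and a gene was called changed at an adjusted p below 0.05. All fold changes are on the log2 scale and given with their standard error (SE), and group levels are means with the standard deviation (SD) of 3 mice.

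There were 28 gene lists, each with at least 5 tested members. They covered marrow cell types: erythroid, early neutrophil granule, late neutrophil, monocyte and macrophage, B cell, plasma cell, T and NK cell, megakaryocyte and platelet, stem and progenitor cell, eosinophil with basophil and mast cell, stroma with bone and vessel, and skeletal muscle. They also covered heme synthesis and iron, p53 targets, the Fanconi anemia and homologous recombination genes, DNA replication, mitosis, type I interferon, interferon gamma, MHC class II, NF-kB and inflammatory cytokines, toll-like receptor signalling, and oxidative stress. The remaining lists were immediate early and handling stress, the unfolded protein and integrated stress response, cytosolic ribosomal proteins, oxidative phosphorylation, and leukemia-associated homeobox genes and oncogenes. A list was called shifted when limma's camera, with a preset correlation of 0.01 between genes, gave an adjusted p below 0.05 over the 28 lists. Beside each call stand the camera p with a correlation estimated from the data and the number of members that passed the gene test. Member counts "adjusted over the list alone" correct for the members of that list only. With limma's fry, which asks whether a list's genes move 1 way on balance, adjusted p values below 0.05 were counted as well.

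Genes are named by a rule: Fancc and Fancg, and for each comparison with wild type, or of the double knockout with a single knockout, the 10 largest rises and falls past the threshold. Where none passed, the 3 genes with the smallest p are given as values. For the single knockouts against each other and the interaction, the largest 5 per direction (or the 3 smallest p) are named. From each shifted list in a comparison with wild type, up to 4 members past the threshold are named, or up to 3 with the smallest p as values. The sex-linked genes are named too, and predicted genes were passed over. Comparisons, tests, lists, the naming rule and all alternatives not called added in the text were chosen before the data were examined.

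Alternatives covered the filter (none, or the percentile 75), the probe set of a gene (mean of all, or only unique ones), the scaling of arrays (quantile normalization again, median centring) and the variance model (no trend, robust, no moderation). They also covered array weights, a fit of only the groups compared, the replicate number as a block, Xist as a covariate, and leaving out each array in turn. Added after the values were seen were fits without Fancg-/- replicates 1 and 3, without double-knockout replicates 2 and 3, and without the 332 genes of the sex chromosomes. The first and second of these leave 1 array in that group, which is then taken to vary like the other groups. The overlap of the 3 comparisons with wild type was set beside 50 simulated sets of unchanged groups sharing the same controls. The procedure was tested on simulated data with 200 changed genes per run in 5 runs. It recovered 32.8% of 1.5-fold changes, 85.6% of 2-fold changes and 98% of 3-fold changes, and 5.17% of its calls were false. In both simulations the noise was independent between genes and equally wide on every array. The real arrays differed in spread (array weights 0.27 to 2.33), so these shares and the simulated overlaps may not carry over to them. Figures were drawn with matplotlib 3.10.9.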

Results

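Fancc and Fancg encode subunits of the Fanconi anemia core complex, which acts in the repair of DNA crosslinks. The marrow of 12 mice was profiled: 3 wild type, 3 Fancc-/-, 3 Fancg-/- and 3 double-knockout mice, with 1 array per mouse and 11908 genes tested. The question of the design is how the loss of either gene, or of both, alters gene expression in whole marrow. The arrays were alike in overall signal, with medians between 4.79 and 4.87. Correlations within groups were 0.990 to 0.995 in wild type, 0.981 to 0.991 in Fancc-/-, 0.992 to 0.995 in Fancg-/- and 0.986 to 0.994 in the double knockout, against 0.975 to 0.994 between groups. Double-knockout replicate 1 was at 0.987 and 0.986 with replicates 2 and 3 of its group. With Fancg-/- replicates 1 and 2 it was at 0.994 and 0.992, so the double-knockout arrays did not form 1 close group. The number of arrays limits the precision.

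The targeted genes were read first. Fancg was at 6.84 ± 0.03 (SD, n = 3) in wild type, 6.57 ± 0.14 in Fancc-/-, 6.40 ± 0.35 in Fancg-/- and 5.74 ± 0.11 in the double knockout. It fell in the double knockout (log2 change -1.10 ± 0.16 SE, limma adjusted p = 0.0105), and its value in Fancg-/- was -0.44 ± 0.16 (adjusted p = 0.567). The Fancg-/- replicates read 6.55, 6.00 and 6.64. A second Fancg probe set gave -0.53 in Fancg-/- and -1.33 in the double knockout. Fancc was at 6.04 ± 0.14, 6.06 ± 0.11, 6.09 ± 0.11 and 5.79 ± 0.22 in the same order, with changes of 0.02 in Fancc-/- and -0.26 in the double knockout that did not pass. Other Fancc probe sets gave 0.46 ± 0.11 (adjusted p = 0.0696) and 0.16 in Fancc-/-, and 0.04 and -0.17 in the double knockout, so the Fancc signal was not lower in its own knockout. Both Fancg probe sets were lower in each double-knockout array (5.61 to 5.83 and 5.41 to 5.67) than in any wild-type array. Fancg-/- replicate 2 was low on both as well (6.00 and 5.92). Replicates 1 and 3 lay within the Fancc-/- range (6.43 to 6.72) on the first probe set, below wild type (6.80 to 6.86). On the second they read 6.43 and 6.67, below wild type (6.82 to 6.92) and, for replicate 3 only just, below Fancc-/- (6.68 to 6.78). In those replicates the signal was thus lower than in wild type, but by less than in replicate 2. It does not show full loss of Fancg. The location of the Fancc and Fancg probe sets relative to the deleted parts is not known, and a probe set outside the deleted part is no check of the genotype.

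Sex-linked transcripts differed between the groups. Xist, the RNA that silences 1 X chromosome in female cells, was at 11.89 ± 0.52 (SD, n = 3) in wild type and 11.69 ± 0.47 in Fancc-/-, but at 6.82 ± 0.73 in the double knockout. The Y-linked gene Eif2s3y was at 3.04 ± 0.15 and 3.14 ± 0.18 in wild type and Fancc-/-, and at 9.00 ± 0.30 in the double knockout. Kdm5d, also Y-linked, was at 3.19 ± 0.10, 3.22 ± 0.15 and 5.44 ± 0.20 in these groups. In Fancg-/-, replicate 2 resembled the double knockout, with Eif2s3y at 9.09 and Xist at 7.34. Replicates 1 and 3 of Fancg-/- had both marks, with Eif2s3y at 7.64 and 5.78 and Xist at 11.3 and 10.7. Sex and genotype therefore cannot be told apart in the comparison of the double knockout with wild type, while wild-type and Fancc-/- mice had the same marks. Every comparison that uses Fancg-/-, and the interaction, also mixes genotype with these marks.

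**Figure D1:**
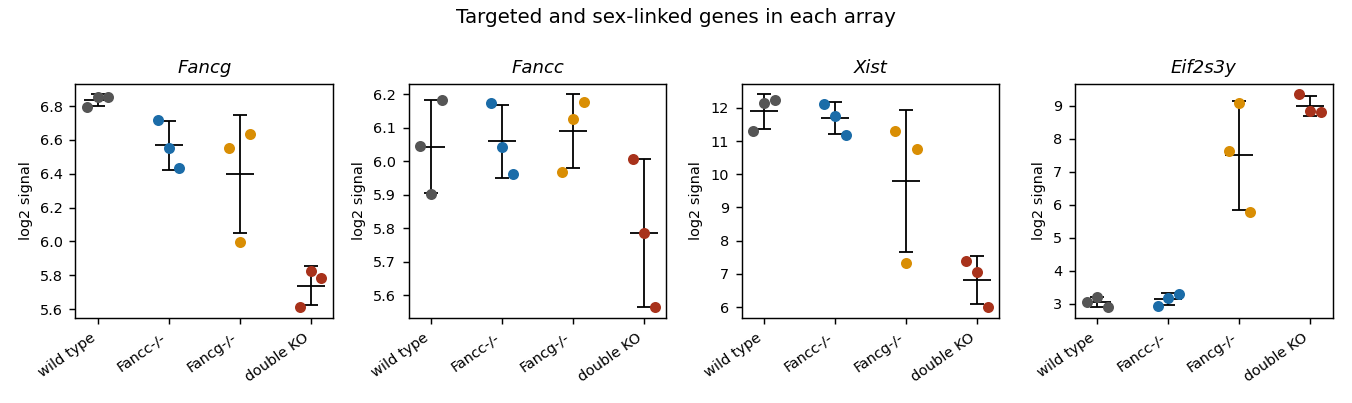
Log2 signal of Fancg, Fancc, Xist and Eif2s3y in each array (points), with group mean and SD (bars, n = 3). Fancg is lowest in the double knockout (5.74 ± 0.11), and the Fancg-/- arrays are spread between low and high Xist and Eif2s3y.

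Loss of Fancc was compared with wild type to see what differs in marrow lacking this gene alone. The marrow was not fractionated, so here and below altered cell proportions cannot be told apart from altered expression per cell. Members of different lists may thus change together through 1 cell type. Genes of the B cell list were among the largest falls. Vpreb1, part of the surrogate light chain of the pre-B-cell receptor, went from 8.85 ± 0.53 (SD, n = 3) in wild type to 4.21 ± 0.08 in Fancc-/- (log2 change -4.64 ± 0.75 SE, limma adjusted p = 0.00648). Erythroid genes rose, with Alas2, the first enzyme of erythroid heme synthesis, going from 11.67 ± 0.24 to 12.89 ± 0.14 (1.22 ± 0.12, adjusted p = 0.000683). Mt2, a metal-binding metallothionein, had the largest rise, from 8.27 ± 0.33 to 11.08 ± 0.73 (2.81 ± 0.28, or 7.02-fold, adjusted p = 0.000683). Of the 11908 genes, 259 rose and 281 fell, 540 in all, with 100 rises and 112 falls larger than 2-fold.

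In the B cell list, 21 of 26 measured members fell and 1 rose (25 and 1 adjusted over the list alone), with a median of -2.24. Besides Vpreb1 these included Vpreb3, also of the surrogate light chain family (-3.99 ± 0.54), Rag1, a recombinase of antigen receptor genes (-3.94 ± 0.60), the B-lineage transcription factor Bach2 (-3.29 ± 0.43), Ebf1, which specifies the lineage (-3.18 ± 0.40), Spib (-2.89 ± 0.48) and the surface marker Ms4a1 (-2.71 ± 0.46). Ighm, the heavy chain of IgM, was the member that rose (0.51, adjusted p = 0.0137), and it was chosen after its values were seen. The list had a camera adjusted p = 1.54e-23, and an adjusted p = 0.203 with an estimated correlation. The other large falls were Niban3 (-3.66 ± 0.48), the immunoglobulin segment Ighv14-2 (-3.49 ± 0.64) and Akap12 (-3.13 ± 0.43). All 9 measured MHC class II genes fell (9 adjusted over the list alone), with a median of -1.30, among them H2-Ob (-2.52 ± 0.43), H2-Oa (-1.67 ± 0.36), H2-DMb2 (-1.66 ± 0.23) and H2-DMa (-1.33 ± 0.34). The median was -0.87 without Fancc-/- replicate 3. That list had a camera adjusted p = 1.24e-10, and an adjusted p = 0.230 with an estimated correlation.

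In the erythroid list, 19 of 27 members rose and 0 fell (25 adjusted over the list alone), with a median of 1.03. Examples were Car1, a red cell carbonic anhydrase (1.75 ± 0.27), Rhag of the Rh complex (1.61 ± 0.28), Tspan33 (1.47 ± 0.18) and Add2, a membrane skeleton protein (1.40 ± 0.22). The list had a camera adjusted p = 1.54e-23, and an adjusted p = 0.230 with an estimated correlation. In the heme synthesis and iron list, 6 of 20 members rose (8 adjusted over the list alone), with a median of 0.63, including the enzymes Fech (1.29 ± 0.17), Cpox (1.14 ± 0.26) and Urod (0.94 ± 0.20). Its camera adjusted p = 5.64e-10 compares with an adjusted p = 0.250 with an estimated correlation. The oxidative stress list shifted up by a median of 0.14, and 3 of 22 members rose (4 rose and 1 fell adjusted over the list alone): Gclm of glutathione synthesis (1.15 ± 0.19), Prdx2, a peroxiredoxin abundant in red cells (0.95 ± 0.13), and Nqo1 (0.67 ± 0.17). Its camera adjusted p = 0.0323 compares with an adjusted p = 0.393 with an estimated correlation, and with 0.0584 without wild-type replicate 3 and 0.0801 and 0.0675 without Fancc-/- replicate 2 or 3. The other named rises were Igk, an immunoglobulin light chain (2.35 ± 0.50), Bex4 (2.00 ± 0.19), Mllt3 (1.97 ± 0.20), the tight junction gene Tjp1 (1.93 ± 0.39), Clca3a1 (1.86 ± 0.39), Prxl2a (1.80 ± 0.26) and Cd59a (1.72 ± 0.39). Armc8 rose as well (1.83 ± 0.24), but its value was -0.17 on probe sets unique to 1 gene.

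Other lists shifted down in Fancc-/- with few members past the gene test. In the eosinophil, basophil and mast cell list, 3 of 14 fell (5 adjusted over the list alone), median -1.48: the basophil protease Mcpt8 (-2.54 ± 0.65), the IgE receptor chain Ms4a2 (-1.57 ± 0.39) and the mast cell protease Cpa3 (-1.39 ± 0.34). Camera gave an adjusted p = 9.58e-05 for it, and an adjusted p = 0.393 with an estimated correlation. On Fancc-/- replicate 3 this list's median was -2.79, against -0.43 and -0.68 on the other arrays, and MHC class II read -1.92 there against -0.80 and -0.84. Of 24 immediate early and handling stress genes, 3 fell (6 adjusted over the list alone), median -0.67, namely Dusp2 (-1.58 ± 0.22), Klf4 (-1.15 ± 0.27) and Gadd45b (-1.07 ± 0.16). The camera adjusted p = 3.31e-06 compares with an adjusted p = 0.496 with an estimated correlation. Of 24 T and NK cell genes, the granzyme Gzma (-1.95 ± 0.44) and Cd2 (-1.61 ± 0.29) fell (4 adjusted over the list alone), median -0.38, camera adjusted p = 0.00152, and adjusted p = 0.496 with an estimated correlation. Of 16 early neutrophil granule genes, Fcnb fell (-1.10 ± 0.28), 1 in all (2 adjusted over the list alone), median -0.24, camera adjusted p = 0.00832, and adjusted p = 0.393 with an estimated correlation. Of 28 NF-kB genes, Cd40 fell (-1.34 ± 0.31), 1 in all (1 adjusted over the list alone), median -0.39, camera adjusted p = 0.0217, and adjusted p = 0.496 with an estimated correlation. Of 29 ribosomal protein genes, Rpl12 (-0.95 ± 0.24) and Rpl37 (-0.75 ± 0.16) fell (2 adjusted over the list alone), median -0.05, camera adjusted p = 0.0232, and adjusted p = 0.496 with an estimated correlation. The stroma, bone and vessel list shifted up by a median of 0.40 with 0 of 17 members past the gene test (0 adjusted over the list alone), camera adjusted p = 0.0250, and adjusted p = 0.545 with an estimated correlation. The ribosomal call was lost without wild-type replicate 1 (adjusted p = 0.112) or Fancc-/- replicate 2 (0.191), and the NF-kB call without wild-type replicate 2 (0.137) or 3 (0.165) or Fancc-/- replicate 2 (0.0929). The stroma call was lost without wild-type replicate 2 (0.120) or 3 (0.0778) or Fancc-/- replicate 2 (0.0594) or 3 (0.0954). Medians also moved by over 1.5 times when 1 array was left out. Without Fancc-/- replicate 3 they were -0.59 (eosinophil, basophil and mast cell), -0.21 (T and NK cell, with 1 member past the gene test) and -0.15 (early neutrophil), and without Fancc-/- replicate 1 the stroma list read 0.64. Without wild-type replicate 1 the NF-kB list read -0.61 and the ribosomal list -0.02, and without wild-type replicate 2 the immediate early list read -0.40 and the NF-kB list -0.26. The stroma values of smallest p were Mgp 1.46 ± 0.67, Ctsk 1.26 ± 0.53 and Adipoq 1.21 ± 0.62.

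The Fancc-/- count was 540 of 11908 by limma, with 2352 genes at an unadjusted p below 0.05, where chance gives 595.4. It was 340, 175 and 226 without wild-type replicate 1, 2 or 3, 250 without variance moderation and 247 in a fit of these 6 arrays alone; of the 46 named calls, 35, 27 and 28 held without wild-type replicate 1, 2 or 3, 34, 44 and 37 without Fancc-/- replicate 1, 2 or 3, and 27 in all of these. Centring arrays on their medians gave 394 rises and 255 falls, and quantile normalization 366 and 252, so the split of rises and falls depends on the scaling.

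**Figure D2:**
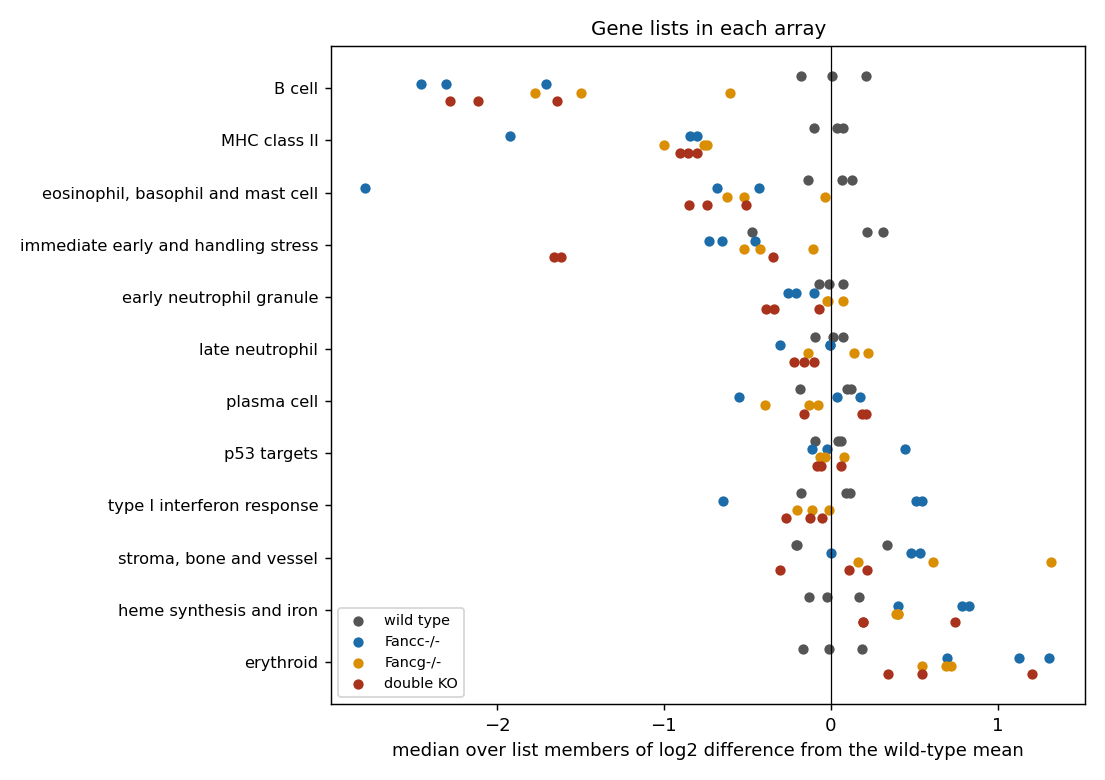
Median over list members of the log2 difference from the wild-type mean in each array (points, colored by group), for a selection of the gene lists. The median changes against wild type, which are not drawn, were -2.24 in Fancc-/-, -1.34 in Fancg-/- and -2.07 in the double knockout for the B cell list. For the erythroid list they were 1.03, 0.68 and 0.66.

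The Fancg-/- group was compared with wild type in the same way, with the limits on replicates 1 and 3 given above. Few genes passed the test: Trib2, a pseudokinase linked to leukemia, fell from 8.16 ± 0.43 (SD, n = 3) to 6.04 ± 0.48 (-2.13 ± 0.25 SE, limma adjusted p = 0.0132). Also lower were Dennd5b (-1.42 ± 0.19), the myosin Myo1e (-0.93 ± 0.14), Fam214a (-0.84 ± 0.11) and Cd209d, a C-type lectin gene (-0.80 ± 0.09, adjusted p = 0.0120). The Y-linked Eif2s3y rose (4.46 ± 0.58, adjusted p = 0.0201), with Kdm5d at 1.09 ± 0.33 and Xist at -2.09 ± 0.80, which did not pass. The B cell list shifted down by a median of -1.34, with 0 of 26 members past the gene test (21 lower adjusted over the list alone), camera adjusted p = 2.35e-30, and adjusted p = 0.0995 with an estimated correlation. Its values included Bach2 at -2.35 ± 0.43 (adjusted p = 0.114), Ebf1 at -2.24 ± 0.40 (adjusted p = 0.0986) and Cd79a, a chain of the B cell receptor, at -1.52 ± 0.28. The list's median was -1.77, -1.5 and -0.61 in replicates 1, 2 and 3, and Vpreb1 read 5.07, 5.88 and 8.92 there.

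The erythroid list shifted up in Fancg-/- by a median of 0.68 with 0 of 27 members past the gene test (20 adjusted over the list alone), camera adjusted p = 2.1e-23, and adjusted p = 0.176 with an estimated correlation. Cldn13 was at 1.05 ± 0.25, Tmod1 at 0.91 ± 0.19 and Tspan33 at 0.84 ± 0.18. Heme synthesis and iron genes had a median of 0.40 with 0 of 20 past the gene test (7 adjusted over the list alone), camera adjusted p = 6.24e-08, and adjusted p = 0.230 with an estimated correlation, with Urod at 0.67, Fech at 0.62 and Glrx5 at 0.52. MHC class II genes had a median of -0.80 with 0 of 9 past the test (7 lower adjusted over the list alone), camera adjusted p = 1.86e-12, and adjusted p = 0.176 with an estimated correlation, with H2-Ab1 at -1.01, H2-Eb1 at -0.93 and their regulator Ciita at -0.68. Stroma, bone and vessel genes had a median of 0.68 with 0 of 17 past the test (0 adjusted over the list alone), camera adjusted p = 1.31e-08, and adjusted p = 0.176 with an estimated correlation. Mmp13 was at 2.73 ± 0.92, Cxcl12 at 2.09 ± 0.70 and Adipoq at 1.96 ± 0.62, and the list's median was 1.32, 0.61 and 0.17 in replicates 1, 2 and 3, and 0.36 without replicate 1.

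Other lists were called by camera in Fancg-/-, again with 0 members past the gene test except Trib2. The immediate early list had a median of -0.41 (1 lower adjusted over the list alone; Dusp2 -0.73, Jund -0.56, Gadd45b -0.32), camera adjusted p = 1.87e-05, and adjusted p = 0.498 with an estimated correlation. Plasma cell genes had a median of -0.14 (2 lower adjusted over the list alone), with Irf4 at -1.42, Mzb1 at -0.93 and Slamf7 at -0.73, camera adjusted p = 0.000436, and adjusted p = 0.411 with an estimated correlation. Stem and progenitor genes had a median of -0.12 (2 lower adjusted over the list alone), with Sox4 at -1.5, Myb at -0.53 and Flt3 at -0.51, camera adjusted p = 0.0375, and adjusted p = 0.338 with an estimated correlation. The leukemia-associated list had a median of -0.04, and Trib2 fell in it (4 adjusted over the list alone), camera adjusted p = 0.00715, and adjusted p = 0.176 with an estimated correlation. Eosinophil, basophil and mast cell genes had a median of -0.43 (0 adjusted over the list alone; Fcer1a -1.12, Ms4a2 -0.81, Gata2 -0.57), camera adjusted p = 0.00768, and adjusted p = 0.498 with an estimated correlation. Oxidative stress genes had a median of 0.07 (1 higher adjusted over the list alone; Gclm 0.63, Prdx2 0.58, Txnrd1 0.22), camera adjusted p = 0.0046, and adjusted p = 0.176 with an estimated correlation. Oxidative phosphorylation genes had a median of 0.11 (0 adjusted over the list alone), with Cyc1 at 0.27, Atp5o at 0.25 and Cox5b at 0.22, camera adjusted p = 2.21e-05, and adjusted p = 0.436 with an estimated correlation. Mitosis genes had a median of 0.13 (0 adjusted over the list alone; Ccnb2 0.37, Ccna2 0.36, Cdca8 0.23), camera adjusted p = 0.00138, and adjusted p = 0.627 with an estimated correlation. DNA replication genes had a median of 0.10 (0 adjusted over the list alone; Tk1 0.34, Chaf1b 0.30, Rfc4 0.26), camera adjusted p = 0.00766, and adjusted p = 0.627 with an estimated correlation. Ribosomal protein genes had a median of -0.03 (0 adjusted over the list alone; Rpl12 -0.53, Rpl37 -0.41, Rps27 -0.17), camera adjusted p = 0.0460, and adjusted p = 0.587 with an estimated correlation. Calls lost on leaving out 1 array were the ribosomal list (wild-type replicate 1, adjusted p = 0.365; Fancg-/- replicates 2 and 3, 0.0905 and 0.0791) and DNA replication (wild-type replicate 3, 0.199). So were the stem and progenitor list (wild-type replicates 1 and 3, adjusted p = 0.0813 and 0.105, and Fancg-/- replicate 3, 0.181) and the eosinophil, basophil and mast cell list (wild-type replicate 3, 0.0862, and Fancg-/- replicate 3, 0.295). Medians that moved by over 1.5 times without wild-type replicate 1 were immediate early (-0.66), mitosis (0.22), oxidative stress (0.12), oxidative phosphorylation (0.17), leukemia-associated (-0.11), stem and progenitor (-0.01) and ribosomal (0.00). Without wild-type replicate 2 these were immediate early (-0.19), eosinophil, basophil and mast cell (-0.20), plasma cell (-0.06) and leukemia-associated (-0.07). Without wild-type replicate 3 they were immediate early (-0.25), plasma cell (-0.27), mitosis (0.08), DNA replication (0.04) and leukemia-associated (-0.07). Of the Fancg-/- arrays, replicate 1 moved the leukemia-associated (-0.10) and ribosomal (-0.02) lists, replicate 2 the plasma cell (-0.24), oxidative stress (0.14), leukemia-associated (-0.01) and ribosomal (-0.02) lists, and replicate 3 the immediate early (-0.26) and oxidative stress (0.04) lists.

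The Fancg-/- count was 6 genes by limma (1 rise, 5 falls), with 834 at an unadjusted p below 0.05. It was 0 without wild-type replicate 1 or 2 or Fancg-/- replicate 1, 3 without wild-type replicate 3, 31 without Fancg-/- replicate 3, 72 in a fit of these 6 arrays alone, 277 with array weights and 0 with Xist as a covariate. With that covariate the median SE went from 0.154 to 0.198, and the values were Trib2 -2.17 ± 0.33, Dennd5b -1.53 ± 0.24, Myo1e -0.95 ± 0.18, Fam214a -0.91 ± 0.15, Cd209d -0.75 ± 0.11 and Eif2s3y 3.50 ± 0.59. Their adjusted p values were 0.213 to 0.385, so these calls were lost, with a wider SE and, for Eif2s3y, a smaller change. Of the 6 calls, 2 held without wild-type replicate 3, 4 and 5 without Fancg-/- replicate 2 or 3, and 0 without wild-type replicate 1 or 2 or Fancg-/- replicate 1.

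Loss of both genes was compared with wild type. Genes of the B cell list fell again, with Rag1 going from 7.38 ± 0.45 (SD, n = 3) to 3.46 ± 0.46 (-3.92 ± 0.60 SE, limma adjusted p = 0.0111). Mt2 rose from 8.27 ± 0.33 to 10.85 ± 0.12 (2.58 ± 0.28, adjusted p = 0.00382), and the amino acid enzyme Asns, a target of the integrated stress response, rose from 8.55 ± 0.12 to 9.90 ± 0.17 (1.35 ± 0.17, adjusted p = 0.00624). The immediate early genes Egr1 (-2.35 ± 0.52), Jun (-2.09 ± 0.40), Fos (-1.81 ± 0.36) and Klf2 (-1.79 ± 0.41) fell. In all, 270 genes rose and 359 fell, with 80 rises and 138 falls larger than 2-fold. Centring arrays on their medians gave 374 rises and 370 falls, and quantile normalization 276 and 373, so the split depends on the scaling.

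In the B cell list, 21 of 26 members fell in the double knockout and 0 rose (25 adjusted over the list alone), with a median of -2.07, camera adjusted p = 8.75e-20, and adjusted p = 0.312 with an estimated correlation. They included Vpreb1 (-3.82 ± 0.75), Vpreb3 (-3.27 ± 0.54), Bach2 (-2.91 ± 0.43), Igll1, the other surrogate light chain gene (-2.58 ± 0.47), and Spib (-2.48 ± 0.48). Niban3 (-3.31 ± 0.48), Akap12 (-2.83 ± 0.43) and Ptgs2, the inducible cyclooxygenase (-3.09 ± 0.79), were the other large falls besides Xist (-5.08 ± 0.80). Of 9 MHC class II genes 5 fell (8 adjusted over the list alone), median -0.87, among them H2-Ob (-1.67 ± 0.43), Ciita (-1.08 ± 0.17), H2-DMb2 (-0.96 ± 0.23) and H2-Eb1 (-0.88 ± 0.22), camera adjusted p = 2.33e-06, and adjusted p = 0.328 with an estimated correlation. The erythroid list had 8 of 27 members that rose (18 adjusted over the list alone), median 0.66, among them Add2 (1.28 ± 0.22), Tmod1 (1.18 ± 0.19), Cldn13 (1.06 ± 0.25) and Icam4 (0.96 ± 0.22), camera adjusted p = 2.16e-12, and adjusted p = 0.328 with an estimated correlation. Of 20 heme synthesis and iron genes 6 rose (7 adjusted over the list alone), median 0.37, among them Urod (0.88), Abcb6 (0.87), Fech (0.72) and Glrx5 (0.70), camera adjusted p = 0.000187, adjusted p = 0.466 with an estimated correlation, and adjusted p = 0.0737 without double-knockout replicate 1, where the median was 0.19. The list read 0.75, 0.19 and 0.19 in replicates 1, 2 and 3.

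Stress-related lists also shifted in the double knockout. Of 24 immediate early genes 9 fell (19 adjusted over the list alone), median -1.19, camera adjusted p = 7.54e-11, and adjusted p = 0.328 with an estimated correlation. This list read -0.34, -1.66 and -1.62 in double-knockout replicates 1, 2 and 3, and the 18S ribosomal 5' control probe set read 12.2, 10.6 and 8.88 on the same arrays. Of 29 unfolded protein and integrated stress response genes, Asns, Slc7a11 and Trib3 rose, 3 in all (8 rose and 1 fell adjusted over the list alone), median 0.17, camera adjusted p = 0.011, and adjusted p = 0.736 with an estimated correlation. Slc7a11 (2.38 ± 0.43), a cystine transporter, and Trib3 (2.11 ± 0.44) were among the largest rises. Without wild-type replicate 1 or double-knockout replicate 2 this list had an adjusted p = 0.135 or 0.15. It read -0.05, 0.46 and 0.04 in double-knockout replicates 1, 2 and 3, and its median was 0.02 without replicate 2 and 0.29 without replicate 1. Of 22 oxidative stress genes 5 rose (7 adjusted over the list alone), median 0.10, including Slc7a11, Sod2 (0.79), Gclm (0.73) and Prdx2 (0.68), camera adjusted p = 0.011, and adjusted p = 0.328 with an estimated correlation, and its median was 0.18 and 0.07 without double-knockout replicate 2 or 3. Other large rises were Emp1 (3.25 ± 0.63), the phosphatase Dusp16 (2.50 ± 0.51), Rhov (2.33 ± 0.47), Cbr3 (2.09 ± 0.45), Plagl1 (2.06 ± 0.39) and the Y-linked Eif2s3y (5.96 ± 0.58) and Kdm5d (2.26 ± 0.33).

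Some early neutrophil and progenitor genes fell in the double knockout. Of 16 early neutrophil granule genes 4 fell (4 adjusted over the list alone), median -0.30: the transcription factor Gfi1 (-1.42 ± 0.30), Ms4a3 (-0.61 ± 0.13), and the granule proteins Elane (-0.33 ± 0.07) and Mpo (-0.31 ± 0.07). Camera gave an adjusted p = 0.00287, and an adjusted p = 0.328 with an estimated correlation. Of 24 stem and progenitor genes 3 fell (1 rose and 3 fell adjusted over the list alone), median -0.22: Sox4 (-1.97 ± 0.37), Myb (-1.26 ± 0.19) and Erg (-1.17 ± 0.29), camera adjusted p = 0.0352, and adjusted p = 0.328 with an estimated correlation. Of 25 leukemia-associated genes Sox4, Trib2 (-1.62 ± 0.25) and Myc (-0.76 ± 0.20) fell, 3 in all (6 adjusted over the list alone), median -0.17, camera adjusted p = 0.011, and adjusted p = 0.328 with an estimated correlation. Of 26 late neutrophil genes Mcemp1 fell (-0.59 ± 0.14), 1 in all (1 adjusted over the list alone), median -0.08, camera adjusted p = 0.0221, and adjusted p = 0.852 with an estimated correlation. The eosinophil, basophil and mast cell list had a median of -0.68 with 0 of 14 past the gene test (2 adjusted over the list alone), and Ms4a2 at -1.43, Cpa3 at -0.94 and Il5ra at -0.58, camera adjusted p = 0.011, and adjusted p = 0.631 with an estimated correlation. Of 28 DNA replication genes Chaf1b, a chromatin assembly factor, rose (0.59 ± 0.14), 1 in all (2 adjusted over the list alone), median 0.13, camera adjusted p = 0.00193, and adjusted p = 0.736 with an estimated correlation. Of 33 oxidative phosphorylation genes Ndufa5 rose (0.49 ± 0.12), 1 in all (0 adjusted over the list alone), median 0.15, camera adjusted p = 2.56e-05, and adjusted p = 0.470 with an estimated correlation. Calls lost on leaving out 1 array were the late neutrophil list (wild-type replicates 2 and 3, adjusted p = 0.173 and 0.0658, and double-knockout replicate 2, 0.0819), the stem and progenitor list (wild-type replicates 1 and 3, 0.0509 and 0.0714, and double-knockout replicate 2, 0.0805), and the eosinophil, basophil and mast cell list (double-knockout replicate 1, 0.0538). The late neutrophil median moved to -0.17 and -0.05 without wild-type replicate 1 or 2, and to -0.20, -0.14 and -0.13 without double-knockout replicate 1, 2 or 3. The DNA replication median was 0.20 and 0.07 without wild-type replicate 1 or 3, and the oxidative phosphorylation median 0.24 without wild-type replicate 1 and 0.09 without double-knockout replicate 2.

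The double-knockout count was 629 by limma (2876 at an unadjusted p below 0.05); it was 134, 16 and 56 without wild-type replicate 1, 2 or 3, 1853, 58 and 19 without double-knockout replicate 1, 2 or 3, and 34 without double-knockout replicates 2 and 3, an alternative added after the values were seen. It was 39 without variance moderation, 3382 with array weights 593 without sex-chromosome genes (also added then), and 0 with Xist as a covariate. That covariate nearly coincides with the group and raised the median SE from 0.154 to 0.332, so calls were lost even where the value was about as large, as for Mt2 (2.51 ± 0.63) and Asns (1.65 ± 0.37), while others such as Cbr3 were smaller as well (1.06 ± 0.92). The adjusted p was above 0.99 for these 3 genes. The list medians were then -1.63 (B cell), -0.80 (MHC class II), 0.72 (erythroid) and -0.98 (immediate early), with 0 members past the gene test. Of 53 named calls, 22, 3 and 13 held without wild-type replicate 1, 2 or 3 and 52, 19 and 5 without double-knockout replicate 1, 2 or 3, and Eif2s3y, Mt2 and Asns held in all of these.

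**Figure D3:**
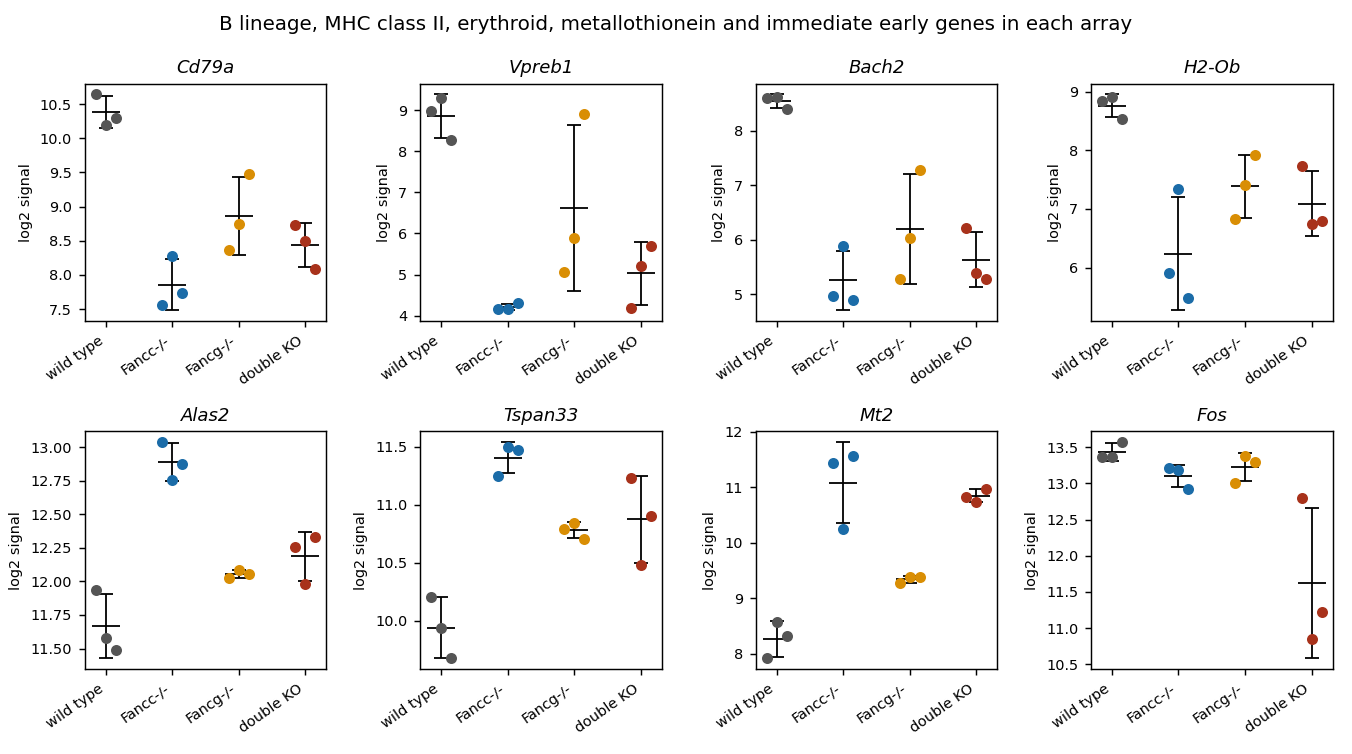
Log2 signal of 8 named genes in each array (points) with group mean and SD (bars, n = 3). Vpreb1 falls from 8.85 in wild type to 4.21 in Fancc-/- and 5.04 in the double knockout, while Mt2 is at 11.08 and 10.85 there against 8.27 in wild type.

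The 3 comparisons with wild type were then set side by side. Of the 540 genes changed in Fancc-/- and the 629 changed in the double knockout, 208 changed in the same direction in both (99 rose, 109 fell) and 0 in opposite directions. Independent lists would share 14.3. At an unadjusted p below 0.01 the shared genes were 404, against 60.0 for independent lists and a mean of 19.6 (highest 32) in simulated unchanged groups with the same controls. For Fancc-/- and Fancg-/- these were 210, 12 and 18.8 (highest 27), and for Fancg-/- and the double knockout 193, 15.3 and 18.5 (highest 33). Cd209d, Dennd5b, Fam214a, Myo1e and Trib2 fell in all 3 comparisons. Across genes, which are not independent replicates, the correlation of log2 changes between Fancc-/- and the double knockout was 0.615 against a simulated 0.504, with a covariance of 0.0991 against 0.0195. Between Fancc-/- and Fancg-/- it was 0.741 against 0.5 (covariance 0.0723 against 0.0193), and between Fancg-/- and the double knockout 0.648 against 0.501 (0.0684 against 0.0193). All comparisons share the 3 wild-type arrays, too few to split into separate control sets, so part of the excess of shared genes over independent lists may come from shared controls. The simulated groups share those controls but hold no real changes, and their genes vary independently, so their range may be too narrow.

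The single knockouts were compared directly. All Fancc-/- arrays had female marks, while Fancg-/- replicate 2 had male marks and replicates 1 and 3 had both. Sex and genotype therefore cannot be told apart in this comparison. Eif2s3y (4.36 ± 0.58), the protease inhibitor Cst3 (0.76 ± 0.12) and Rgs2 (0.60 ± 0.09, adjusted p = 0.0369) were higher in Fancg-/- than in Fancc-/-. Lower in Fancg-/- were Mt2 (-1.74 ± 0.28; 9.34 ± 0.06 against 11.08 ± 0.73, SD, n = 3), Bex4 (-1.5 ± 0.19, adjusted p = 0.0247), Mllt3 (-1.28 ± 0.20) and Mkrn1 (-0.92 ± 0.14). Armc8 was lower as well (-1.59 ± 0.24), but at 0.11 on unique probe sets. Limma called 13 genes (3 higher, 10 lower), with 1076 at an unadjusted p below 0.05. The count was 0 without Fancc-/- replicate 1 or Fancg-/- replicate 1, 1 without Fancg-/- replicate 2 or 3, 32 without Fancc-/- replicate 2, 51 without Fancc-/- replicate 3 and 0 in a fit of these 6 arrays alone.

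The double knockout was compared with each single knockout to see what loss of the second gene adds. Against Fancc-/-, Eif2s3y rose (5.87 ± 0.58, limma adjusted p = 0.0039), and the next values were Xist at -4.87 ± 0.80, Ccndbp1 at -0.77 ± 0.12 and the mitochondrial carrier Slc25a39 at -0.64 ± 0.10, each with an adjusted p = 0.0528. All Fancc-/- arrays had female marks and all double-knockout arrays male marks, so sex and loss of Fancg cannot be told apart here either. Against Fancg-/-, 0 genes passed (1714 at an unadjusted p below 0.05, smallest adjusted p = 0.155), with Fnip2 at 1.26 ± 0.18, Odc1 of polyamine synthesis at 0.76 ± 0.13, Lgals8 at 0.65 ± 0.12, the progenitor marker Prom1 at -1.03 ± 0.18, Ms4a3 at -0.77 ± 0.13 and Marveld1 at -0.64 ± 0.13. Against Fancc-/- the count was 1, with 2345 genes at an unadjusted p below 0.05; it was 2 without Fancc-/- replicate 2, 327 without Fancc-/- replicate 3, 1285 without double-knockout replicate 1 and 5 without replicate 3. Against Fancg-/- it was 993 without double-knockout replicate 1 and 1 without Fancg-/- replicate 2, and array weights gave 1727 and 2250.

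The interaction tested whether the double-knockout change departs from the sum of both single-knockout changes. Cd209d passed (1.13 ± 0.12 SE, limma adjusted p = 0.0118): it was at 5.45 ± 0.06 (SD, n = 3) in wild type, 4.44 ± 0.12 in Fancc-/-, 4.65 ± 0.07 in Fancg-/- and 4.78 ± 0.04 in the double knockout. The knockout means lay below the array medians (4.79 to 4.87), so a floor of the signal cannot be told apart from an interaction for this gene. The next values were Alas2 at -1.09 ± 0.18 (adjusted p = 0.0664), Ccndbp1 at -1.03 ± 0.17 and Slc25a39 at -0.83 ± 0.14 (adjusted p = 0.0675). By camera, 6 lists shifted up and 4 down, and 0 with an estimated correlation (smallest adjusted p = 0.375). The B cell list had a median interaction of 1.49 and the erythroid list of -1.02, opposite in sign to the single-knockout changes, with 0 members past the gene test. The count of 1 gene (1771 at an unadjusted p below 0.05) became 5, 0 and 2 without wild-type replicate 1, 2 or 3, 3 and 105 without Fancc-/- replicate 2 or 3, 2, 4 and 21 without Fancg-/- replicate 1, 2 or 3, 594 without double-knockout replicate 1 and 0 without replicate 2 or 3.

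**Figure D4:**
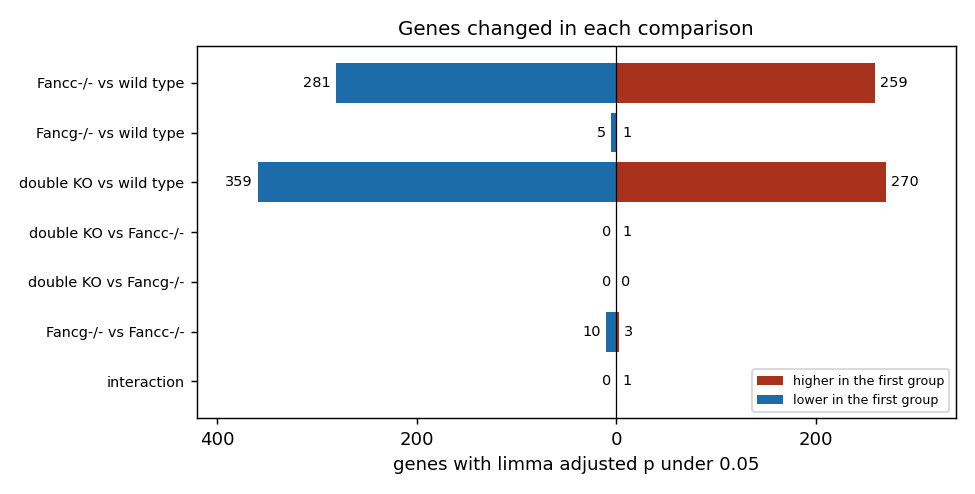
Genes changed in each comparison at an adjusted p below 0.05, with rises to the right and falls to the left. Fancc-/- (259 and 281) and the double knockout (270 and 359) against wild type have nearly all of the calls.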

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

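The tests of the 3 patterns weighed last were chosen after their results were seen, while the interaction, the fits without 1 array and the counts of other splits were planned.

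The interaction marks where the double-knockout change differs from the sum of the single-knockout changes. For Cd209d it was 1.13, and for the lists the medians were 1.49 (B cell), -1.02 (erythroid), 1.27 (MHC class II), -0.66 (heme synthesis and iron), -0.83 (stroma, bone and vessel), -0.36 (mitosis), 0.29 (unfolded protein and integrated stress response), 0.0792 (ribosomal proteins), 0.27 (plasma cell) and 1.03 (eosinophil, basophil and mast cell). None of the list calls held with an estimated correlation, with adjusted p values from 0.375 (B cell, erythroid and MHC class II) to 0.703. Leaving out 1 array ended the calls for the ribosomal list (Fancc-/- replicate 2, adjusted p = 0.0560), the plasma cell list (Fancc-/- replicate 3, 0.315) and the unfolded protein list (Fancc-/- replicate 3, 0.187, or Fancg-/- replicate 3, 0.0544). It also ended the eosinophil, basophil and mast cell call (wild-type replicate 3, 0.0599, Fancc-/- replicate 3, 0.179, Fancg-/- replicate 3, 0.106, or double-knockout replicate 1, 0.0509). Medians moved by over 1.5 times for the eosinophil list without Fancc-/- replicate 3 (0.20) and the stroma list without Fancg-/- replicate 1 (-0.50) or double-knockout replicate 2 (-1.26). So did mitosis without double-knockout replicate 1 (-0.56) and the unfolded protein list without wild-type replicate 1 (0.47) or Fancc-/- replicate 2 (0.45). The plasma cell list read 0.44, 0.41 and 0.46 without wild-type replicate 3, Fancc-/- replicate 2 or Fancg-/- replicate 2, and the ribosomal list 0.04 and 0.05 without wild-type replicate 1 or Fancc-/- replicate 2. Of 100 regroupings of the 12 arrays, counting the real one, 6 gave as many genes (1, with 32 the highest other). As many lists came from 52 (10, with 18 the highest other), so chance is not excluded for either.

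For the other comparisons, 10 splits of 6 arrays are too few for a share below 0.05. The numbers of splits as large, given in brackets, include the real grouping itself. The real counts and the highest of the other splits were 540 and 1 for Fancc-/- against wild type (1 split as large), 6 and 0 for Fancg-/- (1 split), 629 and 1 for the double knockout (1 split), 13 and 0 for the single knockouts (1 split), and 0 and 0 for the double knockout against Fancg-/- (10 splits). For the double knockout against Fancc-/- they were 1 and 1054 (2 splits). The split with 1054 genes put Fancc-/- replicate 3 with double-knockout replicates 2 and 3, against the rest, which points to a structure of the samples other than genotype. For the lists they were 12 and 16 in Fancc-/- (6 splits as large), 15 and 17 in Fancg-/- (2 splits) and 14 and 16 in the double knockout (3 splits).

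Fancg-/- replicates 1 and 3 carried both Xist and Eif2s3y. Exchange of a whole sample is argued against, since their Eif2s3y lay at least 1.17 log2 units from every array of the other groups. RNA of male and female cells in 1 sample may account for it, since both marks stood at least 2.48 log2 units above the highest array lacking them. If wild-type RNA were the female part, genes changed in both other knockouts would lie between wild type (0) and Fancg-/- replicate 2 (1). Replicate 1 lay at 1.06 (interval 1.01 to 1.13, 134 genes) and replicate 3 at 0.687 (0.610 to 0.739). These intervals cover the spread among genes only, and 1 mouse sets the upper end of the scale. Only genes at least 0.5 log2 units from wild type in that mouse were used. A mouse with larger changes, mixed with wild-type RNA, could lie at the same positions, so the positions alone decide nothing. On the linear scale, Eif2s3y in replicate 1 was at 37.1% of the double-knockout mean and Xist at 64.3% of the wild-type mean. Wild-type RNA at a share near that of Xist would keep much of the B cell signal. The B cell list, however, read -1.77 there, against -0.18 to 0.21 in wild type, and Vpreb1 5.07, against 8.27 to 9.30. For these genes the values argue against wild-type RNA as the female part of replicate 1. It stays open for replicate 3. In replicate 3, made from 0.91 µg of RNA, Vpreb1 (8.92) lay within the wild-type range and Rag1 (6.53) below it (6.94 to 7.84). Its arrays' correlation with wild-type replicate 1 was 0.9943, the highest between groups. With Fancg-/- replicates 1 and 2 it was 0.9916 and 0.9920. Fancg itself was higher in replicate 1 (6.55) than in replicate 2 (6.00). RNA of another female mouse with Fancg, such as Fancc-/-, stays untested. So does any biological explanation, although the labels state that RNA was not pooled.

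Immediate early genes were lowest in double-knockout replicates 2 and 3 (-1.66 and -1.62) and at -0.34 in replicate 1, where the list was still called with that array alone (camera adjusted p = 0.000327, and 0.814 with an estimated correlation). The list's deviations from group means went with the 18S 5' control over the 12 arrays (r = 0.777, rho = 0.846, exact permutation p = 0.01 for r and 0.0108 for rho over 1296 permutations, and r = 0.657 without the 2 farthest arrays), so RNA quality or processing may contribute. The 5' minus 3' controls did not set double-knockout replicate 2 apart. Actin read -0.26, -0.29 and -0.42 in double-knockout replicates 1, 2 and 3, against -0.32 to -0.21 in wild type. Gapdh read 0.07, 0.07 and -0.03, against -0.06 to 0.12. A difference between samples that the labels do not give, such as handling time, cannot be told apart: the list's median was 0.290 of its size without those replicates, which restates the values above. Nor can a genotype effect, since 1 of 3 double-knockout arrays lay within the wild-type range. Sex, which also differs from wild type, stays untested.

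The B cell and erythroid lists moved in the double knockout by less than the sum of the single knockouts. In the erythroid list, 22 of 27 members had a level expected from adding both changes below 12.3, the 99th percentile of tested genes. Their median interaction was still -1.05 (-1.28 to -0.802), which argues against a ceiling of the signal for them. This interval and the next cover the spread among genes only. Between double-knockout mice the erythroid list ran from 0.35 to 1.21. A floor for the B cell list cannot be told apart from the rest. The 12 of 26 members with an expected level above 4.83, the mean array median, may still include dim ones. They gave 1.33 (0.753 to 1.65), a part of the list only. A difference of the wild-type mice from all knockout mice other than genotype may also give this, with an interaction equal and opposite to the single-knockout change. The slope was -0.943, but the same group means enter both axes, so it cannot be told apart from both genes acting in 1 pathway.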

How the results depend on the processing

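Among these alternatives, those without Fancg-/- replicates 1 and 3, without double-knockout replicates 2 and 3 and without sex-chromosome genes were chosen after the values were seen; the first 2 leave 1 array in that group, taken to vary like the others. Across all alternatives, values of named genes kept direction and side of the threshold in 2967 instances, lost the call in 689, gained it in 99 and reversed in 10; for lists these were 1304, 146, 57 and 5. The cause of the changes was not tested except where fewer genes or arrays were used. Dim genes limit the depth: 6285 stayed untested.

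Leaving out 1 array gave 175 to 644 genes for Fancc-/- against wild type, 0 to 31 for Fancg-/-, 16 to 1853 for the double knockout, 1 to 1285 for the double knockout against Fancc-/-, 0 to 993 against Fancg-/-, 0 to 51 for the single knockouts and 0 to 594 for the interaction. Lists ranged from 8 to 18, 12 to 18, 11 to 14 and 8 to 14 (Fancc-/-, Fancg-/-, double knockout, interaction).

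In the order Fancg-/- against wild type, double knockout against Fancc-/-, single knockouts, interaction, the main counts were 6, 1, 13 and 1. The stricter filter gave 2 (Fancg-/-), 38 (double knockout against Fancc-/-) and 0 (interaction), and no filter 6 for the interaction. The mean of probe sets gave 10, 21, 1 and 3, and unique probe sets 3, 7, 2 and 0. Quantile normalization gave 19 for the double knockout against Fancc-/-, and median centring gave 19, with 21 for the single knockouts and 4 for the interaction. Without a variance trend the single knockouts gave 1. Without moderation the counts were 250 (Fancc-/-), 2 (Fancg-/-), 39 (double knockout), and 0, 0 and 2 for the last 3. Array weights gave 277 (Fancg-/-), 3382 (double knockout), 1727 and 2250 (double knockout against Fancc-/- and Fancg-/-), 38 and 1035. Fits of the compared groups alone gave 247 (Fancc-/-), 72 (Fancg-/-), 3 (double knockout against Fancc-/-), 2 (against Fancg-/-) and 0 (single knockouts). The replicate block gave 5 (double knockout against Fancc-/-) and 7 (single knockouts). Against wild type it gave 463 for the double knockout and 5 for Fancg-/-, where 3 of the 6 calls were kept. Across all groups, same-number arrays were on average no more alike than others (mean r -0.017 against 0.0067). The same-number pairs of wild type and Fancc-/- read 0.159, 0.146 and 0.158, and their other pairs -0.233 to 0.0475. For wild type and Fancg-/- the same-number pairs read -0.271, -0.063 and -0.365. A pairing of wild type with Fancc-/- thus stays open. With the block that comparison gave 528 genes and kept 463 of its 540 calls. With Xist as covariate the counts were 0 for Fancg-/-, the double knockout, the double knockout against Fancc-/-, the single knockouts and the interaction. An estimated correlation gave 0 lists in all 4 comparisons, and fry 7, 1, 8 and 0.

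Without Fancg-/- replicates 1 and 3 the single knockouts gave 2 genes, the interaction 3 and Fancg-/- 9 lists, and late neutrophil genes read -0.14. Without double-knockout replicates 2 and 3 the count against wild type was 34 and against Fancg-/- 1, and mitosis genes read 0.20. Without sex-chromosome genes the double knockout against Fancc-/- gave 0 and the single knockouts 1.

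Of the reversed genes only Armc8 had been called, and no reversed gene value was past the threshold, while the 5 reversed list values were and had not been called with all arrays. Armc8 read -0.17 in Fancc-/- and 0.11 between the single knockouts on unique probe sets. Kdm5d in Fancc-/- read -0.0027 after quantile normalization and -0.0228 with Xist as covariate, and from -0.0415 (without Fancc-/- replicate 2) to 0.111 (without replicate 1) when 1 array was left out. Fancc ranged from -0.0545 (without wild-type replicate 2) to 0.0848 (without replicate 3) in Fancc-/- and from -0.0236 to 0.116 in Fancg-/- without the same arrays, and read 0.0380 in the double knockout on another of its probe sets. Xist in Fancc-/- ranged from -0.50 (without wild-type replicate 1) to 0.0484 (without Fancc-/- replicate 3). The interferon gamma list ranged from -0.16 (without Fancc-/- replicate 1) to 0.18 (without replicate 3) in Fancc-/-, and from -0.13 (without Fancc-/- replicate 3) to 0.21 (without replicate 2) in the interaction. The immediate early interaction ranged from -0.43 (without double-knockout replicate 1) to 0.33 (without wild-type replicate 1). At an unadjusted p below 0.01 the overlaps were 210 (Fancc-/- and Fancg-/-), 404 (Fancc-/- and double knockout) and 193 (Fancg-/- and double knockout), against simulated means of 18.8, 19.6 and 18.5.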

Other observations

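The genes named in this part, and the strain explanation tested on the locus counts, were chosen after the values were seen; the locus counts were planned.

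Several gene groups often studied in Fanconi anemia did not shift as lists with all arrays. The Fanconi anemia and homologous recombination genes had 0 of 34 members changed by limma in any of the 3 comparisons with wild type, with medians of 0.05 in Fancc-/-, 0.07 in Fancg-/- and -0.07 in the double knockout (camera adjusted p = 0.346, 0.482 and 0.532). The p53 targets had medians of 0.08, -0.02 and -0.05 over 27 genes (camera adjusted p = 0.400, 0.725 and 0.917). Among them the ribonucleotide reductase subunit Rrm2b fell in Fancc-/- (-0.82) and the double knockout (-1.10), Xpc, a damage sensor of nucleotide excision repair, fell in the double knockout (-0.84), and the pro-apoptotic Bbc3 rose there (1.06). Type I interferon genes had medians of 0.11, -0.08 and -0.18 over 31 genes (camera adjusted p = 0.297, 0.132 and 0.201). Interferon gamma genes had medians of -0.06, -0.05 and -0.13 over 22 genes (camera adjusted p = 0.599, 0.716 and 0.601), and Cd274, the ligand of PD-1, rose in the double knockout (1.19). The flat result in Fancc-/- rested on 1 array: the type I list read 0.55 and 0.51 in replicates 1 and 2 and -0.64 in replicate 3. Without replicate 3 its median was 0.51 and 9 of 31 members rose, Irf7, Ifit1, Oasl2 and Usp18 among them (camera adjusted p = 4.02e-11, and 0.139 with an estimated correlation). The interferon gamma list then had a median of 0.18 and 4 of 22 rose (camera adjusted p = 0.0197, and 0.427 with an estimated correlation). Toll-like receptor genes had medians of -0.07, 0.01 and -0.02 over 22 genes (camera adjusted p = 0.274, 0.450 and 0.798), with falls of Irf5 (-0.82), Irak3 (-0.73) and Unc93b1 (-0.55) in Fancc-/- and of Tlr1 (-1.37) in the double knockout. Other flat lists also differed in sign between Fancc-/- arrays. The p53 list ranged from -0.11 to 0.44, the Fanconi anemia list from -0.13 to 0.21 and the toll-like receptor list from -0.22 to 0.15.

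Among the cell types, monocyte and macrophage genes had medians of -0.29, 0.05 and -0.15 (camera adjusted p = 0.293, 0.178 and 0.423). In Fancc-/- the macrophage gene Cd5l rose (1.50) and Klf4 fell (-1.15). Megakaryocyte and platelet genes had medians of 0.11, 0.08 and 0.06 (camera adjusted p = 0.475, 0.743 and 0.917). Skeletal muscle genes had medians of 0.02, 0.08 and -0.09 (camera adjusted p = 0.274, 0.178 and 0.818), and Eno3 rose in the double knockout (0.57). The NF-kB list did not shift in the double knockout (median -0.09, camera adjusted p = 0.542), where the chemokine Ccl3 (-2.00), Ptgs2 (-3.09) and Zfp36 (-1.79) fell and Sod2 rose (0.79). In Fancc-/- the stem and progenitor list did not shift (median -0.08, camera adjusted p = 0.213): the erythroid and megakaryocytic factors Gfi1b (1.41) and Tal1 (1.28) rose while Sox4 (-2.46) and Cd93 (-0.90) fell. The plasma cell list did not shift in Fancc-/- (median -0.04) or the double knockout (0.01), and Irf4 fell in both (-1.54 and -1.35), as did Slamf7 (-0.82 and -0.83). Median and mean had opposite signs for the interferon gamma and unfolded protein lists in Fancc-/-, for the early neutrophil, interferon gamma, toll-like receptor and unfolded protein lists in Fancg-/-, and for the plasma cell, megakaryocyte and muscle lists in the double knockout.

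Genes near a targeted locus can differ when the flanking sequence comes from another strain. In the double knockout, 15 of the 200 tested neighbours of Fancg had changed (7.5%, against 5.24% of other genes), and 8 of 200 for Fancc (4%, against 5.30%). The smaller Fisher exact p was 0.151. In Fancc-/-, where Fancg is not targeted, 13 of its 200 neighbours had changed (6.5%, against 4.50%), the same odds ratio of 1.47. Both comparisons share the wild-type arrays and many calls, so the match itself decides nothing. Flanking sequence cannot be told apart from none with these counts.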
